A study of Mus musculus with 8 samples.

How the data were processed

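RNA was sequenced from 8 mouse libraries, 2 for each of 4 groups: Gr-1+ cells from bone marrow or from skin wounds, of nondiabetic heterozygous (Lepr +/-) or diabetic homozygous (Lepr -/-) mice. Each library came from a pool of 5 mice. The deposited table gives FPKM, which the authors made with TopHat and Cufflinks on the mm9 genome per the submitters' processing notes; no versions or settings are given. It holds 39330 assembled loci, of which 28408 carry a gene name, with a status for every estimate. Only FPKM were available, so the depth of each library is unknown and no counting error could be given. The sum of FPKM ranged from 1544804 to 2788448 over the libraries, and the 10 highest loci took 24.7% to 35.8% of it.

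Of 15578 gene names, 521 were left out because their estimate had a status other than OK in at least 1 library. Among these were S100a8, S100a9, Ngp, Ltf, Cxcl1, Cxcl2, the joint name Lyz1/Lyz2, Csf3r, Csf1r, Fn1, Ccl3, Col1a1, H2-K1 and Xist. A name with several loci (4927 names) was represented by the locus with the highest mean FPKM. Among the names tested, 722 rest on a locus not on the strand of the annotated gene, counting loci of unknown strand, and 672 rest on loci of unknown strand. Genes with FPKM of at least 1 in at least 2 of the 8 libraries were tested, which left 13457. Values were analysed as log2(FPKM + 1) with no further scaling.

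All 8 libraries entered 1 linear model with a mean for each group and 4 residual degrees of freedom, fitted in limma 3.58.1 under R 4.3.3 with a spread that depends on the level (trend = TRUE, robust = FALSE). Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 13457 genes with a threshold of 0.05. The 5 contrasts were wound minus marrow in each genotype, diabetic minus nondiabetic in each tissue, and the difference between the diabetes effects of the tissues (wound minus marrow). Every p-value of this model measures spread between pools, not between mice. Differences are given on the log2 scale with the standard error of the fit (SE), and levels as mean FPKM ± SD of 2 pools (n = 2).

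A total of 38 gene lists of cell type markers, pathways and functions was tested with camera in limma, with a preset correlation between genes of 0.01, for the 37 lists with at least 5 tested members. P-values were adjusted over the lists of a contrast. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, were run beside it. The lists held 744 tested genes, 71 of them in more than 1 list. Of the 15 mitochondrial transcripts listed, 2 were in the table, so that list was not tested. Of 8 sex-linked genes, 1 was in the table (Xist), listed at 16.1 to 34.4 FPKM with a failed estimate in 7 of 8 libraries. None of the Y-linked genes listed was in the table. The labels give sex-matched mice of both sexes, which could not be checked in the data.

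Genes to be named were set by rule. For each contrast the rule took the 12 largest positive and the 12 largest negative differences among genes past the threshold, with a mean FPKM of at least 10 in the higher group and no overlap between the libraries of the groups compared (overlap was allowed for the difference between tissues). Unnamed gene models, small RNA and immunoglobulin or T cell receptor segments were left out of that part. It also took up to 4 members of each list with the smallest p. Lepr, Ly6g, Ly6c1, Ly6c2, S100a8, S100a9 and sex-linked genes were taken in every group, and Hoxa3, Arg1, Il1b, Tnf, Chi3l3, Cxcl1, Cxcl2 and Cxcr2 in every contrast. Of the genes taken by size, those whose locus is under 200 bp or is not on the annotated strand are mostly given as a count, a choice made after seeing the data.

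The groups, contrasts, tests, lists, rule for named genes and first set of alternative settings were chosen before the data were examined. These settings were pseudocounts of 0.1 and 5, no filter and a stricter filter, quantile and median-ratio scaling, a fit without trend and a robust fit, the 2 groups compared alone, summed loci, no small RNA or receptor segments, a block for pool number, a minimum difference of 1 on the log2 scale, each library left out in turn, and the estimated correlation. The settings added after seeing the data kept failed estimates, tested loci without a gene name, took the locus on the annotated strand, or left out loci under 200 bp. The pipeline was tested on simulated data. In the diabetic wound contrast it recovered 84 of 100 genes moved 2-fold and 95 of 100 moved 4-fold, and called 15 of 13221 unmoved genes. For the difference between tissues it recovered 73 of 100 and 92 of 100. Unlike the data, the simulation had independent noise for each gene, few moved genes and no shift in scaling. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.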

Results

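RNA levels were measured by sequencing in Gr-1+ cells, those carrying the myeloid surface antigens Ly6G or Ly6C, which were taken with magnetic beads. They came from bone marrow and from excisional skin wounds, 2 per mouse and 8 mm wide, 3 days after wounding. The 10 nondiabetic mice (Lepr +/-) and the diabetic mice (Lepr -/-) were each divided into pools of 5, giving 2 libraries for each of 4 groups. The depth of the libraries is unknown, since only FPKM were deposited, and named loci with FPKM of at least 1 numbered 11375 to 12380 per library. Spearman correlations across genes were 0.976 to 0.984 between libraries of 1 group, 0.926 to 0.958 between genotypes within a tissue, and 0.644 to 0.673 between tissues. Genes within a library are not independent replicates.

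Lepr, the leptin receptor gene disrupted in the diabetic mice (chromosome 4, 101390009 to 101487957, mm9), was measured at 0.583 ± 0.15 FPKM in nondiabetic marrow, 0.112 ± 0.104 in diabetic marrow, 4.81 ± 0.207 in nondiabetic wound and 1.30 ± 0.107 in diabetic wound (mean ± SD, n = 2 each). By library the values were 0.477 and 0.689, 0.039 and 0.186, 4.95 and 4.66, and 1.37 and 1.22, in the same order. In wound cells Lepr fell by 1.34 with diabetes (SE 0.098, adjusted p = 2.44e-04 by limma). The table gives 1 value per locus, so receptor isoforms cannot be separated, and the labels do not name the allele.

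Among the genes of the sorted antigens, Ly6g fell from 854 ± 64.9 FPKM in nondiabetic marrow to 18.2 ± 1.41 in nondiabetic wound (n = 2), and stood at 568 ± 2.27 and 12.6 ± 0.464 in the diabetic groups. Its diabetes effects were -0.50 in wound and -0.59 in marrow, and their difference of 0.09 did not pass (adjusted p = 0.511) and was negative under both scalings. Ly6c1 and Ly6c2 share a locus with Ly6a, which fell from 2924 ± 76.7 to 142 ± 0.611 FPKM in nondiabetic and from 1714 ± 25.8 to 158 ± 0.395 in diabetic mice. With diabetes it fell by 0.77 in marrow and did not pass in wound (0.15, adjusted p = 0.0773), where it passed in a fit without trend (0.0232), with the wound groups alone (0.0272) and without loci under 200 bp (0.0356). S100a8 and S100a9, which encode the neutrophil protein calprotectin, were listed at 0 in all 4 marrow libraries with a status saying that there were too many reads to estimate, so they could not be compared. In wound libraries S100a8 was measured at 1008 and 994 FPKM in nondiabetic and 774 and 762 in diabetic pools, and S100a9 at 5864, 6378, 4956 and 4970.

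The comparison of wound with marrow asks how Gr-1+ cells at the wound differ from those in their tissue of origin. Marker lists of several cell types differed between the tissues, as given below, and wounds were dissociated with enzymes per the labels. A change within cells therefore cannot be told apart from another mix of cells or from handling. In nondiabetic mice, transcripts of granule proteins were far lower in wound cells. Camp, the antimicrobial peptide cathelicidin (chromosome 9, 109749889 to 109751970), fell from 14078 ± 106 to 7.54 ± 1.19 FPKM (log2 -10.69, SE 0.131, adjusted p = 3.79e-08, n = 2), and Mpo, the granule enzyme myeloperoxidase, from 217 ± 1.71 to 0.22 ± 0.039 (-7.48, SE 0.035). In the opposite direction, Spp1, the secreted protein osteopontin (chromosome 5, 104864137 to 104870069), rose from 7.57 ± 0.729 to 1458 ± 52.1 FPKM (7.41, SE 0.192, adjusted p = 3.79e-07). Tnf, an inflammatory cytokine, rose from 3.60 ± 0.219 to 567 ± 10.9 (6.95, SE 0.043), Il1b, interleukin 1 beta, by 4.80, and Arg1, an arginine-degrading enzyme of repair macrophages, by 6.67. In diabetic mice the differences were -10.59 for Camp, -7.09 for Mpo, 9.01 for Spp1, 5.62 for Tnf, 3.94 for Il1b and 8.41 for Arg1. The plot of 12 genes by library gives each pool's level.

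**Figure D1:**
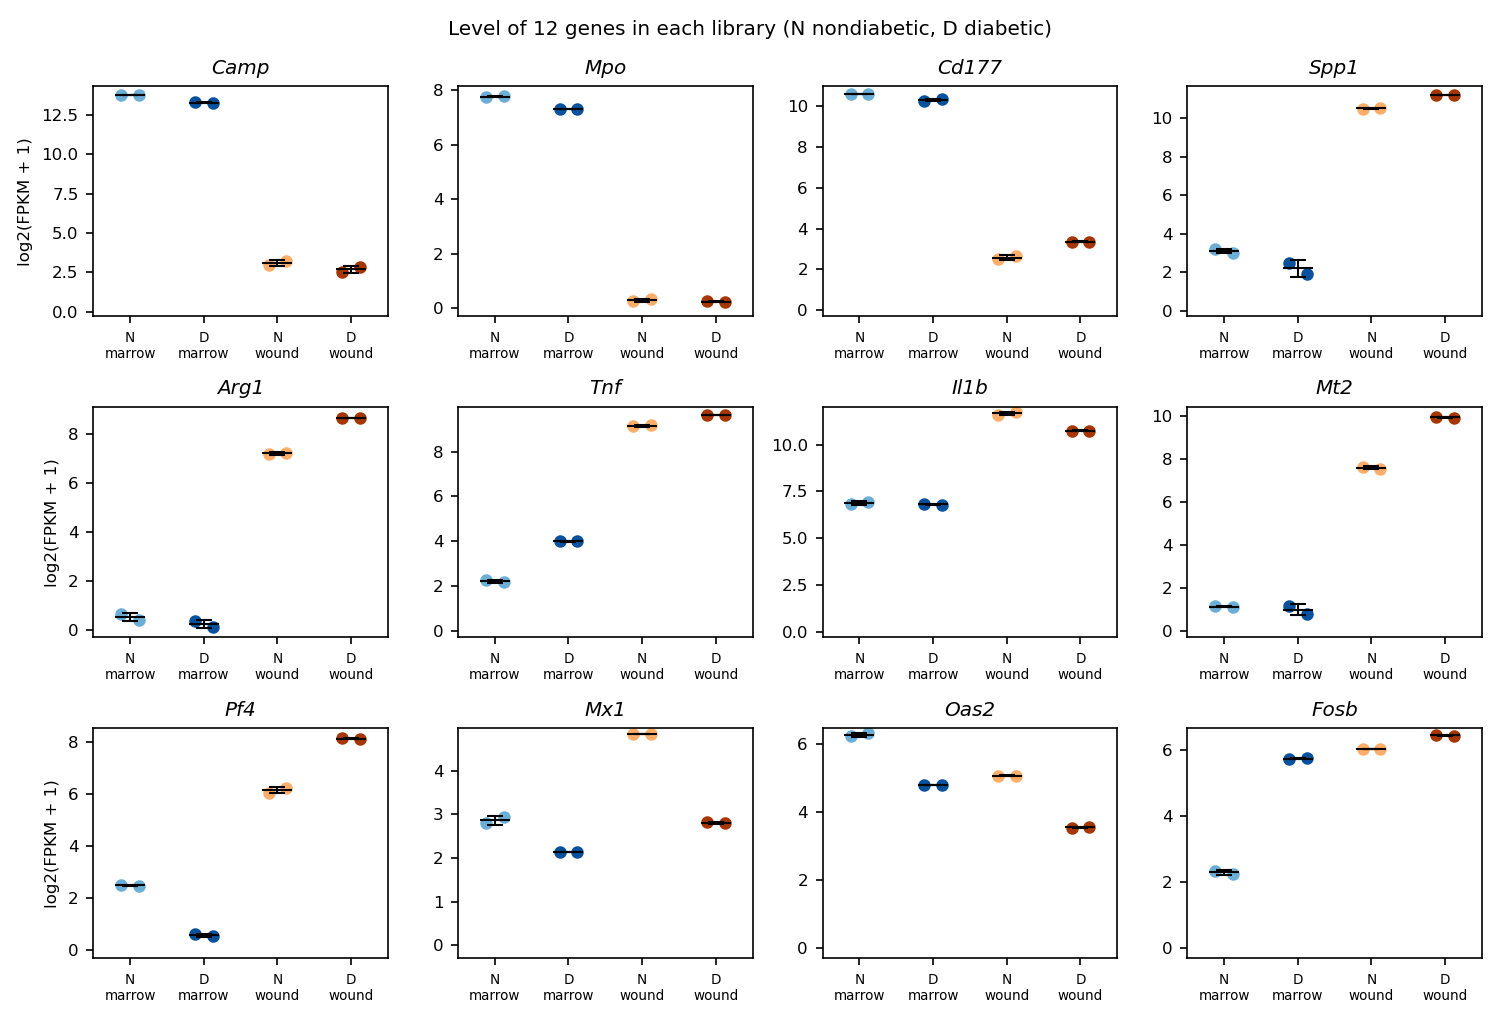
Level of 12 genes in each of the 8 libraries, as log2(FPKM + 1) on the vertical axis, with a point per library and a bar for the mean ± SD of each group (N nondiabetic, D diabetic). Camp, Mpo and Cd177 sit lower in wound than in marrow, Spp1, Arg1, Tnf, Il1b and Mt2 sit higher in wound, and Mx1 and Oas2 sit lower in the diabetic pools of both tissues.

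The large decreases from nondiabetic marrow to wound included Cd177, a neutrophil surface protein (-8.00, SE 0.064; 1523 ± 4.2 to 4.96 ± 0.502 FPKM), Itgb2l, an integrin of the secondary granule list (-7.29), and Ceacam10 (-6.42). The eosinophil granule genes Prg2 (-8.95), Ear1 (-8.68) and Ear6 (-7.25) and the haemoglobin gene Hbb-b1 (-7.80) also fell. Large increases were in Ccrl2, a chemokine-binding receptor (7.62, SE 0.089), Fam71f2 (7.51), Rgs1, a regulator of G protein signalling (7.48), Ptgs2, the prostaglandin-making enzyme COX-2 (7.20), Tnfaip3, a brake on NF-kB (7.08), Cd83, a marker of activated antigen-presenting cells (7.04), and Saa3, an acute-phase protein (6.83). In diabetic mice the largest also included Mt2, a metal-binding metallothionein (8.96, SE 0.112; 0.997 ± 0.346 to 985 ± 17.6 FPKM), Ccl7, a monocyte-attracting chemokine (8.03), Saa3 (7.99), Pf4, platelet factor 4 (7.54), and the keratin locus Krt5/Krt6a/Krt79 (7.60). The basophil proteases Prss34 (-6.16) and Mcpt8 (-6.08) were lower. Of the 24 genes taken by size in each genotype, 5 and 4 rest on a locus that is not on the annotated strand.

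In the neutrophil granule lists, most members fell; counts adjusted over the list alone are given wherever they differ from those over all genes. Of 12 primary granule genes 11 fell and 1 rose in nondiabetic cells (median -2.95, adjusted p = 0.00394 by camera, adjusted p = 0.32 with an estimated correlation), and 9 fell and 2 rose in diabetic cells (-2.81, 0.0125, adjusted p = 0.395 with an estimated correlation). Of 22 secondary and tertiary granule genes, 19 fell in nondiabetic and 20 in diabetic cells and 2 rose in each (medians -4.33 and -4.26, adjusted p = 6.35e-05 and 7.73e-06, adjusted p = 0.465 and 0.395 with an estimated correlation), with Fcnb at -6.38 and Mmp25 at -4.18 in nondiabetic cells. The neutrophil core list did not pass in either genotype: of 22 members 14 fell and 7 rose in nondiabetic cells (median -1.34, adjusted p = 0.32), with Mmp8 (-5.50) and Mmp9 (-4.53), both collagen- or gelatin-cutting proteases, down and Clec4e, a receptor for microbial glycolipids, up (3.47). In diabetic cells 15 fell and 6 rose (-1.33, 0.0773). S100a8, S100a9 and Csf3r of the core list were left out for their status, so its result does not cover them. In every marrow library S100a8 and S100a9 had too many reads to estimate. Ngp and Ltf, other granule genes, had no estimate in pool 2 of either marrow group.

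Inflammatory lists rose. Of 22 NF-kB targets, 22 rose in each genotype (medians 3.80 and 3.09, adjusted p = 1.98e-11 and 3.90e-09, adjusted p = 0.0861 and 0.11 with an estimated correlation), among them Nfkbia, the NF-kB inhibitor (5.00 in nondiabetic cells), and Zc3h12a, an RNase that degrades cytokine messages (3.89). Of 22 chemokines 21 rose in each (2.50 and 3.63, adjusted p = 2.79e-09 and 1.85e-08, adjusted p = 0.0997 and 0.11 with an estimated correlation), such as Cxcl10, which attracts T cells (6.19). Of 22 pro-inflammatory cytokine genes 19 rose and 2 fell in nondiabetic cells and 18 and 3 in diabetic cells (2.42 and 3.21, adjusted p = 2.16e-08 and 7.39e-06, adjusted p = 0.104 and 0.136 with an estimated correlation), such as Csf3, the granulocyte growth factor (4.64). Cxcl1 and Cxcl2, neutrophil-attracting chemokines, had no estimate in diabetic wound pool 1; in the other 3 wound libraries Cxcl1 was at 1055, 1101 and 2873 FPKM. Their receptor gene Cxcr2 fell by 2.65 and 3.21 in nondiabetic and diabetic mice, on a locus of the other strand, and by 3.02 and 2.97 on the annotated strand.

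Genes of tissue repair also rose. Of 26 alternative activation and repair genes 24 rose in nondiabetic and 23 in diabetic cells (medians 2.80 and 2.86, adjusted p = 1.40e-09 and 1.17e-07, adjusted p = 0.0861 and 0.11 with an estimated correlation), such as Areg, an epidermal growth factor family ligand (5.54), and Il10 (4.50). In the same list Chi3l3, a chitinase-like protein measured jointly with Chi3l7, fell by 6.13 and 4.13. Of 26 matrix remodelling genes 20 rose and 5 fell in each genotype (3.14 and 3.25, adjusted p = 1.47e-06 and 1.33e-05, adjusted p = 0.161 and 0.229 with an estimated correlation), such as Tgm2, a protein cross-linking enzyme (5.23). Macrophage genes rose (20 of 22 in each; 2.63 and 2.34, adjusted p = 2.70e-08 and 6.72e-07, adjusted p = 0.108 and 0.136 with an estimated correlation), with Lgmn, a lysosomal protease, at 4.60. Dendritic cell genes rose (14 and 13 of 15; 1.77 and 1.49, adjusted p = 5.33e-06 and 4.64e-04, adjusted p = 0.108 and 0.204 with an estimated correlation), with Ccr7, the lymph node homing receptor, at 6.02. Monocyte genes passed in diabetic cells (10 of 15 higher, 4 lower, median 0.93, adjusted p = 0.0374, adjusted p = 0.395 with an estimated correlation), a call that ended under median-ratio scaling (0.0519). In nondiabetic cells 8 were higher and 5 lower (0.36, 0.119), and Cd14, the lipopolysaccharide co-receptor, was at 6.20.

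Markers of skin cells were higher in the wound libraries, beside all of these groups. All 19 keratinocyte genes rose in each genotype (medians 1.62 and 2.58, adjusted p = 2.16e-08 and 4.14e-08, adjusted p = 0.108 and 0.111 with an estimated correlation), with Lgals7, an epithelial galectin, at 4.44. Fibroblast genes rose (23 of 23, and 22 of 23; 2.46 and 2.28, adjusted p = 1.33e-10 and 2.78e-08, adjusted p = 0.0861 and 0.11 with an estimated correlation), with the collagen gene Col3a1 at 6.31. Endothelial genes rose (17 and 19 of 20; 1.54 and 2.30, adjusted p = 1.49e-06 and 9.61e-07, adjusted p = 0.0861 and 0.11 with an estimated correlation), with Cdh5, a cadherin of vessel walls, at 2.84. The muscle and fat list did not pass (4 and 5 of 9 higher, 3 lower in each, adjusted p = 0.433 and 0.413).

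Antigen presentation, stress and early-response genes were higher in wound cells. MHC class II genes rose (13 and 10 of 14, with 0 and 4 lower; medians 2.40 and 2.25, adjusted p = 1.99e-06 and 0.0096, adjusted p = 0.161 and 0.403 with an estimated correlation), with H2-Ab1 at 3.36. Immediate early genes, which also respond to enzymatic dissociation, rose (23 and 16 of 24, with 1 and 6 lower; 2.61 and 1.57, adjusted p = 7.17e-10 and 0.00139, adjusted p = 0.134 and 0.395 with an estimated correlation), with the transcription factor gene Egr1 at 5.00. Wounds were dissociated with enzymes per the labels. Endoplasmic reticulum stress genes rose (14 and 15 of 17, with 3 and 1 lower; 0.46 and 1.37, adjusted p = 2.91e-04 and 1.90e-05, adjusted p = 0.108 and 0.111 with an estimated correlation), with Ppp1r15a, a stress-induced phosphatase subunit, at 5.86. Lysosome genes rose (21 and 26 of 37, with 15 and 10 lower; 0.54 and 0.93, adjusted p = 0.00962 and 4.64e-04, adjusted p = 0.532 and 0.416 with an estimated correlation), as did interferon-response genes (23 of 36 in each, with 12 and 10 lower; 0.38 and 0.65, adjusted p = 0.00275 and 0.00718, adjusted p = 0.484 and 0.569 with an estimated correlation). Hypoxia and glycolysis genes passed with 15 and 16 of 30 higher and 12 and 7 lower (0.32 and 0.82, adjusted p = 0.0335 and 0.02, adjusted p = 0.587 and 0.609 with an estimated correlation), with Vegfa, the vessel growth factor, at 4.10; in nondiabetic cells the call ended without a filter (0.0535) or with unnamed loci (0.0578). Apoptosis genes passed in nondiabetic cells (13 of 23 higher, 8 lower, 1.03, adjusted p = 0.0486, adjusted p = 0.484 with an estimated correlation) but not under quantile (0.0692) or median-ratio scaling (0.141), with unnamed loci (0.0775) or without nondiabetic marrow pool 2 (0.0586), and had adjusted p = 0.192 in diabetic cells.

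Proliferation and mitochondrial genes were lower in wound cells. Of 34 cell cycle genes 33 and 32 fell (medians -2.53 and -1.80, adjusted p = 1.52e-07 and 6.72e-07, adjusted p = 0.108 and 0.137 with an estimated correlation), with Ccna2, cyclin A2, at -3.76 in nondiabetic cells. Of 33 oxidative phosphorylation genes 31 fell in nondiabetic cells (-1.04, adjusted p = 6.35e-05, adjusted p = 0.32 with an estimated correlation) and 23 fell and 3 rose in diabetic cells (-0.36, 0.0276, adjusted p = 0.585 with an estimated correlation), where the call ended with the stricter filter (0.132), under median-ratio scaling (0.536) and without diabetic wound pool 1 (0.0586), and the median was 0.02 under quantile scaling. Cholesterol synthesis genes fell in nondiabetic cells (18 of 21; -1.07, adjusted p = 0.00463, adjusted p = 0.108 with an estimated correlation), a call that ended with the stricter filter (0.0523), and not in diabetic cells (9 lower, 6 higher; -0.08, 0.992). Erythroid and megakaryocyte genes fell (14 of 16 in each; median -2.47 in each, adjusted p = 0.00463 and 0.00251, adjusted p = 0.225 and 0.229 with an estimated correlation), as did B and plasma cell genes in diabetic cells (14 of 17; -1.68; 0.00816, adjusted p = 0.27 with an estimated correlation) and chromatin modifiers in diabetic cells (23 of 30; -0.74; 0.0096, adjusted p = 0.395 with an estimated correlation). The erythroid, B cell and chromatin calls ended with the stricter filter, as did that of primary granule genes in diabetic cells, and the chromatin call also under quantile scaling (0.0545). In nondiabetic cells 13 B and plasma cell genes fell (-1.78, 0.118) and 20 chromatin genes fell (-0.76, 0.133).

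The remaining lists passed in neither genotype. In nondiabetic and diabetic cells the median was 0.11 and -0.46 for T and NK cell genes (adjusted p = 0.254 and 0.622), -1.67 and -2.33 for eosinophil, basophil and mast cell genes (0.293 and 0.0784), -0.14 and -0.67 for stem and progenitor genes (0.775 and 0.602), and -0.38 and -0.82 for chemokine and adhesion receptors (0.711 and 0.63). It was -0.20 and 0.58 for fatty acid and lipid genes (0.207 and 0.231), -1.15 and -0.20 for oxidative burst genes (0.899 and 0.778), -0.39 and 0.17 for ribosomal protein genes (0.396 and 0.239), -0.03 and 0.10 for Hox cluster genes (0.87 and 0.778), and 0.24 and -0.41 for leptin and insulin signalling genes (0.251 and 0.778). Median, mean or test differed in sign for receptors and oxidative burst genes in both genotypes, for fatty acid genes in nondiabetic cells, and for leptin signalling and cholesterol synthesis genes in diabetic cells. Hox cluster genes differed in sign in both. Hoxa3, a homeobox gene measured on a 313 bp locus, passed in none of the 5 contrasts (wound minus marrow in nondiabetic cells passed without nondiabetic wound pool 2, at 1.08, adjusted p = 0.035).

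Over 13457 genes, limma called 11469 changed between wound and marrow in nondiabetic mice, 4317 higher and 7152 lower, and 6501 of them differed by at least 1 on the log2 scale. In diabetic mice 11332 changed, 4996 higher and 6336 lower, 6278 of them by at least 1. The median of all genes was -0.38 and -0.18, and 0.07 in each with median-ratio scaling, so the split depends on scaling: with median-ratio scaling 5826 were higher and 5293 lower in nondiabetic mice, and 5918 and 5350 in diabetic mice. In all, 9572 genes changed the same way in both genotypes (3811 higher, where 1603 would be expected if the calls were independent, and 5761 lower, where 3367 would be), and 617 changed in opposite ways. Camera called 23 lists in nondiabetic and 24 in diabetic mice with the preset correlation and 0 with an estimated one, where 13 and 10 lists had an unadjusted p under 0.05; fry called 35 in each.

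The comparison of diabetic with nondiabetic wound cells asks how diabetes alters Gr-1+ cells at an early wound. Here and throughout, an effect of diabetes is the difference between Lepr -/- and Lepr +/- pools. It cannot be told apart from an effect of losing the leptin receptor in the cells themselves. Interferon-response genes were lower in diabetic wound cells. Of 36 members 33 fell and 2 rose (median -1.001, adjusted p = 9.56e-18 by camera, adjusted p = 0.293 with an estimated correlation). Mx1, an antiviral GTPase (chromosome 16, 97668642 to 97684514), fell from 27.7 ± 0.056 to 6.00 ± 0.094 FPKM (log2 -2.04, SE 0.053, adjusted p = 1.35e-05, n = 2). Oas2, a double-stranded RNA sensor (-1.52), Ifit2, which binds viral RNA (-1.54), and the Oas1a/Oas1g locus (-1.36) also fell, while Irf1, an interferon-induced transcription factor, was at 232 FPKM in nondiabetic and 391 in diabetic wound cells.

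Among the genes taken by size, those of mast cell proteases were the largest increases on a locus of at least 200 bp: the joint Mcpt1/Mcpt2 transcript rose from 26.8 ± 5.42 to 604 ± 8.19 FPKM (4.46, SE 0.311, adjusted p = 2.05e-04), and Mcpt2 (chromosome 14, 56660960 to 56663471) from 16.2 ± 1.22 to 326 ± 11.8 (4.25). Both share 1 assembled locus with other mast cell proteases. In marrow the joint Mcpt1/Mcpt2 transcript also rose, from 0.25 and 1.43 to 10.36 and 9.32 FPKM (2.63, adjusted p = 1.69e-03), while Mcpt2 was at 0.186 ± 0.263 and 0.556 ± 0.786 FPKM. Ldhb, a lactate dehydrogenase subunit, rose by 3.54 (SE 0.378). Decreases were in Dmbt1, a scavenger receptor of epithelia (10.5 ± 0.689 to 0.015 ± 0.014 FPKM; -3.50, SE 0.059), Acvrl1, a receptor of the TGF-beta family (-2.32), the Padi3/Padi4 locus, of which Padi4 citrullinates histones in neutrophils (-2.28), Apobec3, an antiviral deaminase (-1.95), Klrb1b/Klrb1c, NK cell receptors (-1.91), and Chaf1b, a histone chaperone subunit (-1.88). Of the 24 genes taken by size, 11 were not on the annotated strand and 7 rest on an unstranded locus under 200 bp.

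Arg1 and genes for inflammation and migration moved in different directions. The alternative activation and repair list did not pass. Arg1 rose from 146 ± 5.21 to 402 ± 3.16 FPKM (1.45), and Tnf by 0.47, while Il1b fell from 3269 ± 212 to 1718 ± 20.7 (-0.93). Chemokines rose (15 of 22 and 4 fell, 16 and 5 adjusted over the list alone; median 0.82, adjusted p = 0.00284, adjusted p = 0.347 with an estimated correlation), with Ppbp, a platelet and neutrophil chemokine (3.02, SE 0.068), Pf4 (1.98), Cxcl5, a neutrophil attractant (1.96), and Ccl24, an eosinophil attractant (1.91). Pro-inflammatory cytokine genes fell (14 of 22, 5 rose; -0.29, 0.0123, adjusted p = 0.413 with an estimated correlation), with the cytokine subunits Ebi3 (-1.25) and Il12a (-1.07) down and Csf3 up (1.34). That call ended with the stricter filter (0.072). NF-kB targets fell (13 of 22, 3 rose; -0.34, 7.27e-04, adjusted p = 0.293 with an estimated correlation), with the survival gene Birc3 at -0.99 and Nfkbia at -0.62. Chemokine and adhesion receptors fell (17 of 27, 18 adjusted over the list alone, 6 rose; -0.42, 1.41e-04, adjusted p = 0.413 with an estimated correlation), with Ccr7 falling from 99.7 to 29.1 FPKM (-1.74) and Selplg, a selectin ligand on a 692 bp locus, at -1.26. Cxcr2 did not differ on the annotated strand (18.4 and 18.4 FPKM, adjusted p = 1), whereas its locus on the other strand was at -0.57.

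Cell type markers shifted as well. The H2 genes of the MHC class II list lie in the H2 region, where another haplotype in the diabetic mice is weighed below. Its effect on their values was not tested. MHC class II genes fell (11 of 14, 1 rose; median -0.75, adjusted p = 8.79e-06, adjusted p = 0.293 with an estimated correlation), with H2-Ab1 going from 193 to 67.1 FPKM (-1.51), and so did dendritic cell genes (10 of 15, 11 adjusted over the list alone, 2 rose; -0.53, 7.27e-04, adjusted p = 0.293 with an estimated correlation). Macrophage genes rose (14 of 22, 2 fell; 0.28, 0.0133, adjusted p = 0.413 with an estimated correlation), with the scavenger receptor Marco at 1.33 and the mannose receptor Mrc1 at 0.63. Neutrophil core genes fell (13 of 22, 7 rose; -0.28, 0.0292, adjusted p = 0.604 with an estimated correlation), with Lcn2, an iron-sequestering protein, at -0.96. The macrophage call ended with the stricter filter (0.0566), and the neutrophil core call ended with it, with loci on the annotated strand, and without diabetic wound pool 1 (0.0816). B and plasma cell genes fell with 5 of 17 past the threshold (-0.04, 0.0444, adjusted p = 0.413 with an estimated correlation), a call that ended under 4 alternatives and without diabetic wound pool 2 (0.101).

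Skin cell markers differed between the diabetic and nondiabetic wound pools. Keratinocyte genes rose (15 of 19, 16 adjusted over the list alone, 1 fell; median 0.61, adjusted p = 9.92e-05, adjusted p = 0.293 with an estimated correlation), with Krtdap, a protein of differentiating epidermis, from 9.62 to 37.2 FPKM (1.85) and Krt5/Krt6a/Krt79 at 0.96. Endothelial genes rose (14 of 20, 15 adjusted over the list alone; 0.66, 2.96e-04, adjusted p = 0.293 with an estimated correlation), with the tight junction gene Cldn5 at 2.00 and Plvap, of vessel fenestrae, at 1.13. Fibroblast genes fell (10 of 23, 3 rose; -0.27, 0.00807, adjusted p = 0.4 with an estimated correlation), with Col5a2 at -0.79 and Col3a1 going from 87.4 to 59.0 FPKM (-0.56).

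Metabolic and signalling lists passed as well. Oxidative phosphorylation genes rose (25 of 33; 0.30, 9.92e-05, adjusted p = 0.413 with an estimated correlation), with Ndufv1, a complex I subunit, at 0.41, as did cholesterol synthesis genes (13 of 21, 2 fell, 3 adjusted over the list alone; 0.36, 0.0123, adjusted p = 0.293 with an estimated correlation). Endoplasmic reticulum stress genes rose (12 of 17, 1 fell; 0.38, 0.00514, adjusted p = 0.293 with an estimated correlation), with Manf at 0.70, and ribosomal protein genes with 11 of 25 past the threshold (0.22, 0.0444, adjusted p = 0.604 with an estimated correlation). Leptin and insulin signalling genes fell (10 of 21, 2 rose; -0.14, 0.00514, adjusted p = 0.426 with an estimated correlation), with the signal transducers Stat5a (-0.85) and Stat3 (-0.51), and chromatin modifiers fell with 12 of 30 lower, 13 adjusted over the list alone, and 6 higher (-0.14, 0.028, adjusted p = 0.473 with an estimated correlation), with the DNA methyltransferase Dnmt3a at -0.88. The cholesterol (0.0566), chromatin (0.105) and ribosomal calls ended with the stricter filter, and the ribosomal call also under both scalings and without any 1 of 4 libraries. Single genes of lists that did not pass included the fatty acid transporter Cd36 (64.1 to 275 FPKM, 2.08), Ereg, an epidermal growth factor family ligand (2.26), Hmox1, which degrades haem (1.67), and Ncf1, a subunit of the NADPH oxidase (-1.36).

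The other 18 lists had adjusted p of 0.0781 or more: monocyte, T and NK cell, eosinophil, erythroid, stem cell, muscle and fat, primary and secondary granule, cell cycle, alternative activation, matrix, hypoxia, fatty acid, lysosome, oxidative burst, immediate early, Hox and apoptosis genes. Monocyte genes (median -0.06, mean 0.014) and hypoxia genes (median 0.10, test lower) differed in sign. Limma called 6959 genes changed, 4170 higher and 2789 lower, with 708 differing by at least 1. With median-ratio scaling 3252 were higher and 3700 lower. Camera called 19 lists with the preset correlation and 0 with an estimated one, where 4 had an unadjusted p under 0.05; fry called 32.

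**Figure D2:**
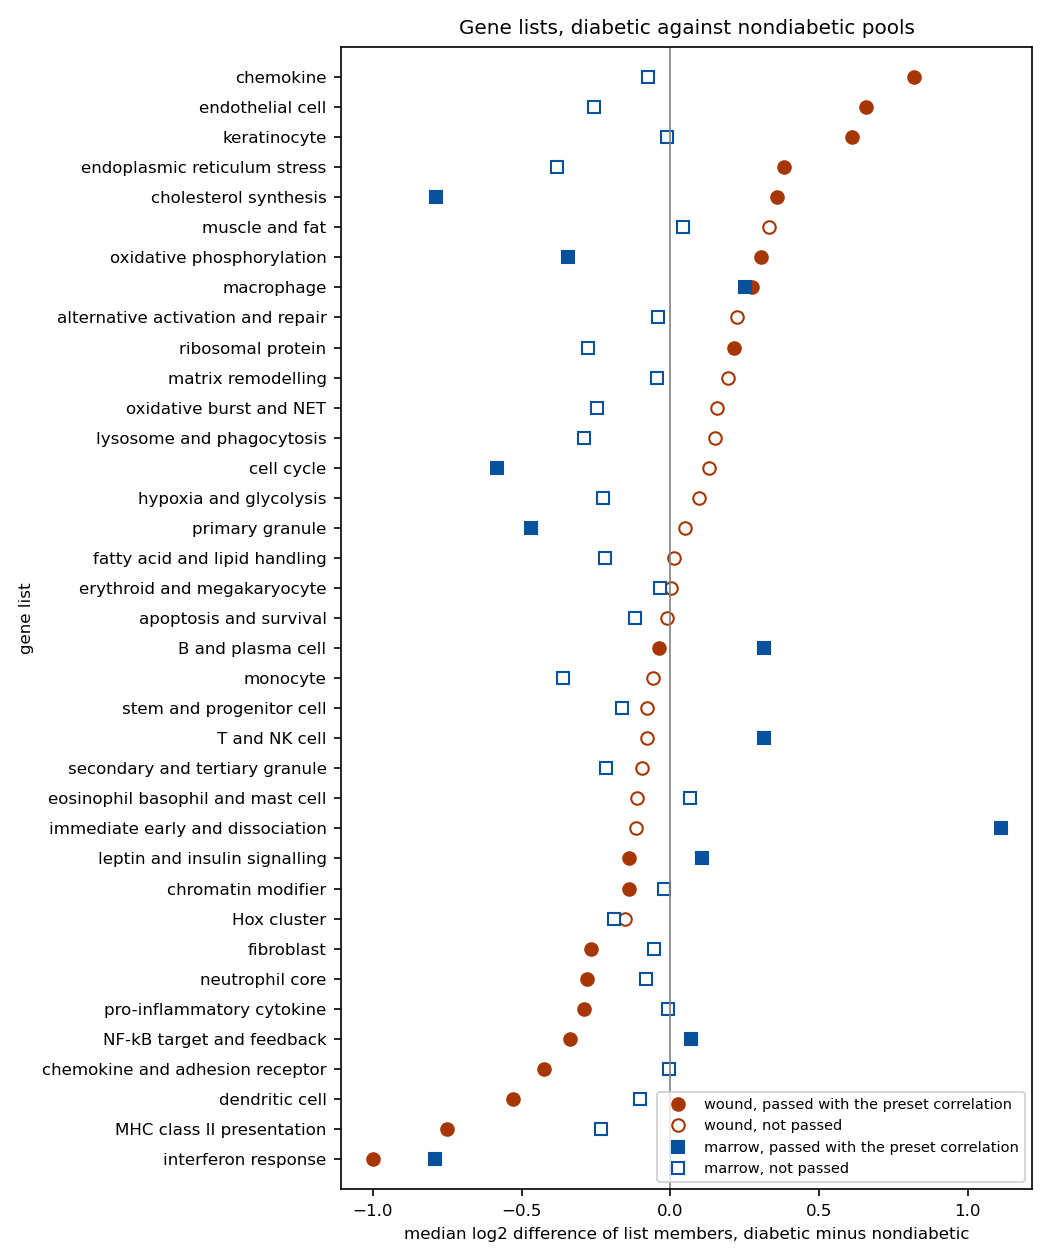
Median log2 difference, diabetic minus nondiabetic, of each of 37 gene lists on the horizontal axis, with circles for wound and squares for marrow; filled symbols passed camera with the preset correlation. Interferon-response genes lie at -1.001 in wound and -0.79 in marrow, and immediate early genes at -0.11 in wound and 1.11 in marrow.

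The same comparison in marrow asks whether diabetes already alters the cells before they reach the wound. Immediate early genes were higher and interferon-response genes lower in diabetic marrow. The immediate early list also holds genes that respond to enzymatic dissociation. A difference in handling between the genotypes was not tested and cannot be told apart from an effect of diabetes. Fosb, a transcription factor of the AP-1 family (chromosome 7, 19888070 to 19895394), rose from 3.93 ± 0.27 to 52.6 ± 0.777 FPKM (3.44, SE 0.044, adjusted p = 2.97e-06, n = 2). Egr1 rose from 11.6 to 59.9 FPKM (2.27), Klf2, a transcription factor of quiescence, by 2.56 and the phosphatase Dusp1 by 1.86. Of 24 immediate early genes 17 rose and 0 fell (median 1.11, adjusted p = 4.11e-13, adjusted p = 0.265 with an estimated correlation). Of 36 interferon-response genes 34 fell and 1 rose (-0.79, 5.79e-13, adjusted p = 0.395 with an estimated correlation), with the Oas1a/Oas1g locus going from 107 ± 0.552 to 22.2 ± 0.363 FPKM (-2.21, SE 0.03), Rtp4 at -1.81, Isg15, a ubiquitin-like modifier, at -1.71 and Oas2 at -1.48. The member that rose, in both tissues, was Xaf1, a promoter of apoptosis (1.55 in marrow and 1.48 in wound), named after its values were seen.

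**Figure D3:**
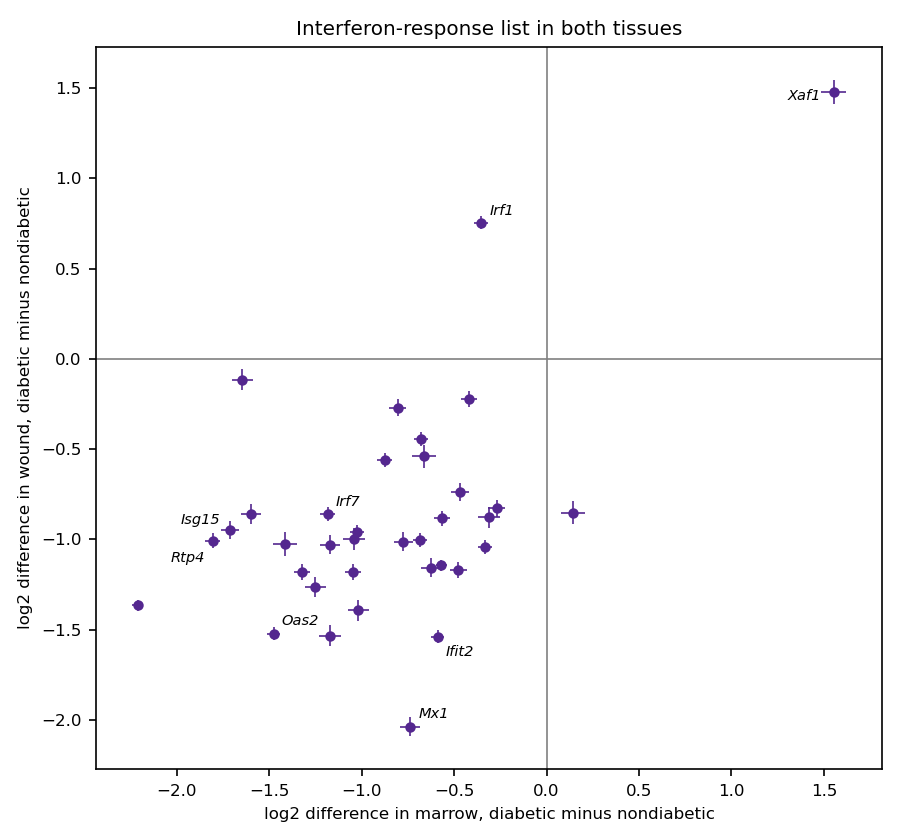
Log2 difference, diabetic minus nondiabetic, of each of 36 interferon-response genes in marrow (horizontal) and wound (vertical), with bars for the SE. In wound 33 genes passed as lower and in marrow 34, while Xaf1 was higher in both (1.48 and 1.55).

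The largest decrease in marrow on the annotated strand was in Acvrl1 (214 ± 4.4 to 2.73 ± 0.622 FPKM; -5.86, SE 0.16, adjusted p = 1.55e-05). Tmem159, a lipid droplet protein (-2.87), Zfp128, a zinc finger gene (-2.61), Ndufs5, a complex I subunit (-2.29), and Ifi27l2a, an interferon-induced gene (-2.12), also fell. The increases included Nsun4, a mitochondrial RNA methyltransferase (3.97, SE 0.341), and the class I histocompatibility locus H2-Gs10/H2-Q7 (233 ± 5.18 to 2389 ± 19.4; 3.36). Chi3l3 fell by 1.88, whereas in wound its difference was 0.11 (adjusted p = 0.128). Tnf rose by 1.80, and Il1b did not pass (-0.07, adjusted p = 0.54). Arg1 did not pass either (-0.28, adjusted p = 0.0753), though it passed without nondiabetic marrow pool 2 (-0.40, 0.0459) or diabetic marrow pool 1 (-0.41, 0.0434). Cxcr2 did not pass (-0.01, adjusted p = 0.99). The signs for Il1b and Cxcr2 turned under both scalings. Of the 24 genes taken by size, 12 were not on the annotated strand and 6 rest on an unstranded locus under 200 bp.

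Proliferation and biosynthesis genes were lower in diabetic marrow. All 34 cell cycle genes fell (median -0.58, adjusted p = 4.09e-10, adjusted p = 0.223 with an estimated correlation), such as Cenpe, a mitotic motor (-0.81), and Cdk1, the mitotic kinase (-0.72). Of 21 cholesterol synthesis genes 20 fell (-0.79, 2.02e-07, adjusted p = 0.132 with an estimated correlation), with Cyp51, a sterol demethylase, at -1.54. Of 33 oxidative phosphorylation genes 29 fell, 30 adjusted over the list alone, and 1 rose (-0.34, 3.01e-05, adjusted p = 0.472 with an estimated correlation), with Cox6a1 at -0.66. Of 12 primary granule genes 10 fell, 11 adjusted over the list alone, and 1 rose (-0.47, 0.00422, adjusted p = 0.472 with an estimated correlation), with Mpo going from 217 ± 1.71 to 159 ± 0.353 FPKM.

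Several immune cell lists were higher. Macrophage genes rose (13 of 22, 6 fell, 7 adjusted over the list alone; 0.25, 4.57e-04, adjusted p = 0.448 with an estimated correlation), with the protease Ctsl at 1.67 and Mrc1 at 1.33. T and NK cell genes rose (10 of 19, 11 adjusted over the list alone, 2 fell; 0.31, 4.57e-04, adjusted p = 0.223 with an estimated correlation), with the adhesion gene Cd2 up (0.69) and the cytotoxic granule gene Nkg7 down (-0.88). B and plasma cell genes rose (9 of 17, 5 fell; 0.31, 0.0108, adjusted p = 0.448 with an estimated correlation), with the B cell receptor genes Cd22 (1.29) and Cr2 (1.56). Leptin and insulin signalling genes rose (9 of 21, 4 fell; 0.11, 0.0165, adjusted p = 0.655 with an estimated correlation), with the feedback inhibitor Socs3 at 0.68, and NF-kB targets rose (8 of 22, 3 fell, 5 adjusted over the list alone; 0.07, 0.0345, adjusted p = 0.472 with an estimated correlation), with Ier3 at 2.05 and Nfkbiz at 1.30. The T and NK cell call ended with the stricter filter (0.399) and the B cell call under median-ratio scaling (0.106) and with a pseudocount of 0.1 (0.0539). Without nondiabetic marrow pool 2 the leptin and NF-kB calls ended (0.0807 each), and without diabetic marrow pool 1 the NF-kB median was -0.03 (0.13). The NF-kB call also ended with unnamed loci (0.079).

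The other 26 lists had adjusted p of 0.0606 or more. Single genes in them that passed included the lipoprotein lipase gene Lpl (1.83) and Cd36 (1.62) upward and the platelet chemokine genes Ppbp (-2.10) and Pf4 (-1.92) downward. Median, mean or test differed in sign for 9 lists: neutrophil core, dendritic, eosinophil, erythroid, keratinocyte, cytokine, receptor, alternative activation and chromatin genes. Limma called 6030 genes changed, 1767 higher and 4263 lower, with 571 differing by at least 1. With median-ratio scaling 2772 were higher and 2510 lower, and with quantile scaling 2251 and 2685. Without diabetic marrow pool 2, 1161 were higher, and without diabetic marrow pool 1, 2794 were lower. Camera called 11 lists with the preset correlation and 0 with an estimated one, where 4 had an unadjusted p under 0.05; fry called 27.

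The difference between the diabetes effects in wound and in marrow asks where the effect depends on the tissue. The platelet chemokine genes Ppbp and Pf4 and most sterol genes differed upward. Ppbp and Pf4 also belong to the erythroid and megakaryocyte list, which did not pass for this difference. Ppbp (chromosome 5, 91197544 to 91199086) went from 5.00 ± 0.501 to 0.399 ± 0.076 FPKM in marrow and from 28.7 ± 0.477 to 241 ± 5.15 in wound (difference 5.12, SE 0.097, adjusted p = 2.82e-05, n = 2), and Pf4 differed by 3.90 (SE 0.091). Of 21 cholesterol synthesis genes 19 differed upward and 0 downward (median 1.22, adjusted p = 3.95e-06, adjusted p = 0.192 with an estimated correlation), with Cyp51 at 2.08. Immediate early genes differed downward (19 of 24, 2 upward, 3 adjusted over the list alone; -1.33, 9.19e-10, adjusted p = 0.274 with an estimated correlation), with Fosb at -3.04, Klf2 at -2.79, Egr1 at -2.33, and the heat shock gene Hspa1b at -3.02.

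Further lists differed upward. Counts are of members past the threshold upward, and the rest did not pass or differed downward. For cell cycle genes 32 of 34 did, 33 adjusted over the list alone (0.76, 2.27e-06, adjusted p = 0.273 with an estimated correlation), with Cdk1 at 0.82, and for oxidative phosphorylation 31 of 33 (0.64, 3.34e-06, adjusted p = 0.329 with an estimated correlation). So did 14 of 19 keratinocyte genes (0.73, 0.00213, adjusted p = 0.329 with an estimated correlation), with Perp, of cell junctions, at 2.01. Of 20 endothelial genes 17 did (0.80, 1.89e-04, adjusted p = 0.273 with an estimated correlation), with Cldn5 at 2.42. Of 22 chemokines 17 did (0.91, 0.00484, adjusted p = 0.329 with an estimated correlation), with Cxcl5 at 2.14. Lysosome genes followed with 24 of 37 (0.47, 0.021, adjusted p = 0.597 with an estimated correlation) and ribosomal protein genes with 16 of 25 (0.56, 0.042, adjusted p = 0.597 with an estimated correlation). The lysosome (0.055) and ribosomal (0.0508) calls ended under median-ratio scaling, and the ribosomal call also without any 1 of 4 libraries (at most 0.0925).

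Other lists differed downward. Unless stated, counts are of members past the threshold downward, and the rest did not pass or differed upward. Of 22 NF-kB targets 13 did (-0.37, 1.29e-05, adjusted p = 0.273 with an estimated correlation), with Nfkbiz at -1.81. Of 27 receptors 17 did (-0.36, 4.10e-05, adjusted p = 0.329 with an estimated correlation), with Ccr7 at -1.78. Of 22 cytokine genes 12 did (-0.42, 8.16e-04, adjusted p = 0.329 with an estimated correlation), with Tnf at -1.33 and Il1b at -0.86. MHC class II genes differed with 9 of 14 (-0.56, 7.47e-04, adjusted p = 0.329 with an estimated correlation), and Ciita, their transcriptional activator, was at -2.11. Dendritic cell genes differed with 10 of 15 (-0.31, 0.00885, adjusted p = 0.329 with an estimated correlation), and leptin and insulin signalling genes with 12 of 21 (-0.29, 7.29e-04, adjusted p = 0.329 with an estimated correlation). Of 17 B and plasma cell genes 10 did (-0.68, 0.00429, adjusted p = 0.329 with an estimated correlation), with Cd22 at -1.51. Of 19 T and NK cell genes 9 did (-0.38, 0.0086, adjusted p = 0.273 with an estimated correlation), with Gzmb, a cytotoxic protease, at -1.55. Neutrophil core genes differed with 11 of 22, 12 adjusted over the list alone (-0.18, 0.0306, adjusted p = 0.597 with an estimated correlation). Fibroblast genes completed the 19 lists, with 9 of 23 downward and 5 upward (-0.17, 0.0394, adjusted p = 0.425 with an estimated correlation).

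The T and NK cell call ended under quantile (0.123) and median-ratio scaling (0.0816) and with the stricter filter, where the median was 0.07 (0.52). The neutrophil core call ended without diabetic wound pool 1 (0.0838), with loci on the annotated strand (0.0545) or with unnamed loci (0.0628), and the fibroblast call under 5 alternatives and without any 1 of 4 libraries (at most 0.0763). With a pseudocount of 0.1 the fibroblast median was 0.05 (0.477).

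Interferon-response genes did not pass for this difference (12 of 36 upward, 15 downward; median -0.03, adjusted p = 0.117), with Irf1 at 1.11 and the Oas1a/Oas1g locus at 0.85. Arg1 differed by 1.74, Chi3l3 by 1.99 and the Ly6c locus by 0.92. Lepr differed by -0.83, but by -0.05 with a pseudocount of 0.1 (adjusted p = 0.94), so the value depends on the pseudocount. Cxcr2 was at -0.56 on the other strand, a call that ended without any 1 of 3 libraries (0.0506 to 0.0574), and at 0.05 on the annotated one. The median, mean or test differed in sign for eosinophil, erythroid and stem cell genes. Of the 24 genes taken by size, 9 were not on the annotated strand. Limma called 7568 genes, 5087 upward and 2481 downward, with 1263 differing by at least 1. With median-ratio scaling 3293 were upward and 3777 downward, and with quantile scaling 3838 and 3360. The median of all genes was 0.19, and -0.003 with median-ratio scaling. Camera called 19 lists with the preset correlation and 0 with an estimated one, where 6 had an unadjusted p under 0.05; fry called 30.

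Across the 13457 genes the diabetes effects in wound and marrow had a Pearson correlation of 0.202 and a Spearman correlation of -0.031, against 0.885 and 0.888 for the tissue effects of the genotypes; genes are not independent replicates. With diabetes, 511 genes were higher in both tissues, where 548 would be expected if the calls were independent, 888 were lower in both (884 expected), 1630 were higher in wound and lower in marrow (1321 expected), and 530 were lower in wound and higher in marrow (366 expected). Among those lower in both were Mx1, Oas2, Acvrl1 and Apobec3, and among those higher in both were Cd36, Mrc1 and Ctsl.

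Of the genes lower or higher by at least 1 in the diabetic pools of both tissues, 22 of 109 lie on chromosome 17, out of 677 tested there. They include 10 transcripts within the span of the H2 genes (34075766 to 37620497), all higher in diabetic pools, a region examined after the values were seen. The map of chromosome 17 shows their positions.

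**Figure D4:**
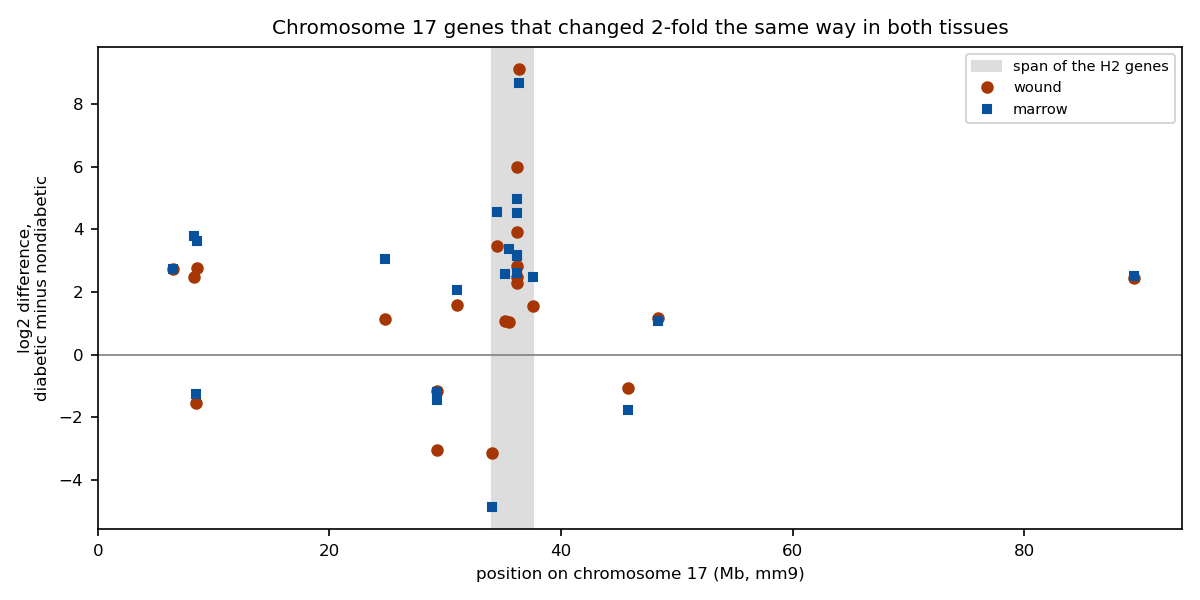
Position on chromosome 17 (Mb, mm9) of the 22 genes that changed 2-fold the same way in both tissues, against the log2 difference, diabetic minus nondiabetic, in wound (circles) and marrow (squares). The grey band is the span of the H2 genes, where all 10 transcripts lie above 0. The symbols below 0 at its left edge are of a transcript that ends at 34042862, before the span begins.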

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

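The comparison of diabetes effects between tissues was planned; the tests of skin cell markers, of the H2 region, of the Lepr region and of class I sums were chosen after the result was seen.

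A total of 7568 genes and 19 gene lists differed in their diabetes effect between wound and marrow by limma or camera with the preset correlation, and 0 lists with an estimated one (6 with an unadjusted p under 0.05; fry called 30). The median differences, wound minus marrow, were 0.911 for chemokines, 0.798 for endothelial, 0.727 for keratinocyte, 0.759 for cell cycle, 0.636 for oxidative phosphorylation, 1.218 for cholesterol synthesis, 0.468 for lysosome and 0.559 for ribosomal protein genes. They were -1.334 for immediate early, -0.684 for B and plasma cell, -0.561 for MHC class II, -0.416 for cytokine, -0.378 for T and NK cell, -0.374 for NF-kB, -0.36 for receptor, -0.314 for dendritic cell, -0.286 for leptin and insulin signalling, -0.184 for neutrophil core and -0.169 for fibroblast genes.

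Single genes whose diabetes effect differed between the tissues, on a locus of at least 200 bp on the annotated strand, were Ppbp (5.12), Ldhb (4.27), Mcpt2 (3.94), Pf4 (3.90) and Acvrl1 (3.54) upward, and Nsun4 (-4.05), Dmbt1 (-3.50), Hspa8 (-3.34), Fosb (-3.04), Hspa1b (-3.02), Lpl (-2.95) and Malat1 (-2.85) downward. Dmbt1 was listed at 0 in diabetic marrow. On loci not on the annotated strand or under 200 bp the differences were 9.45 for Rpl39l, 8.16 for Olfr1217, 4.14 for Sfta2, 3.72 for Slc9a5, 3.44 for Cma2, 3.40 for Rps23, 3.15 for Sox18, -5.64 for Pcsk6, -3.57 for Fstl4, -3.34 for Tdrd9 and -2.83 for Myl6. Rpl39l, Olfr1217 and Slc9a5 were listed at 0 in the other 3 groups, so their values depend on the pseudocount. The Mcpt2 call ended with a pseudocount of 0.1 (adjusted p = 0.139) and that of Rpl39l on the annotated strand (0.727). The Sfta2 call ended under 7 alternatives (0.0501 to 0.0864) and without any 1 of 5 libraries (0.109 to 0.132). That of Slc9a5 ended with a pseudocount of 5 (0.114), with summed loci (0.173), on the annotated strand (0.975) and without single libraries. Those of Myl6 and Sox18 ended without single libraries.

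In wound cells, keratinocyte and endothelial transcripts were higher and fibroblast transcripts lower in the diabetic pools, though the beads select for Gr-1. Of 23 fibroblast genes 10 fell and 3 rose. With an estimated correlation none of these lists passed (adjusted p = 0.293, 0.293 and 0.4 by camera, in the same order). A lower share of the main cell type would raise the markers of every other type alike. The data argue against it as the whole cause. The keratinocyte median exceeded the fibroblast median by 0.881 (permutation p = 1e-05, the smallest possible). The endothelial median exceeded the fibroblast median by 0.926 (permutation p = 1e-05). These permutations shuffled genes as if independent, with the medians known, so their p-values do not measure spread between pools. More keratinocytes carried into the diabetic pools may account for the keratinocyte part, since 15 of 19 members were higher, with Krt14/Krt16 at 109 and 333 FPKM and Krt5/Krt6a/Krt79 at 118 and 229. It cannot be told apart from a change within the cells present, because 1 member fell and the bound was set with the count known. Of the 19 members, 5 reached FPKM of 1 in nondiabetic marrow, and a difference in wound tissue between the genotypes stays open as untested.

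Among loci without a gene name, left out of the comparisons, 6 of at least 200 bp were higher and 3 lower by at least 1 on the log2 scale in the diabetic pools of both tissues, out of 3053 tested. Among named genes 109 changed 2-fold the same way in both tissues, 58 higher and 51 lower. Another haplotype of the H2 region in the diabetic mice is a candidate explanation for part of these. Of its 102 distinct loci 7 are among them, where 0.81 would be expected (Fisher's exact p = 1.60e-05). Counted by transcript they are 10 of 135 (Fisher's exact p = 1.36e-07). The region was examined after its transcripts were seen, and neighbouring loci are not independent draws. These p-values therefore describe the clustering and do not test the haplotype. Only the H2 and Lepr regions were examined in this way. Neighbouring changed genes elsewhere, such as the stefins of chromosome 16, are not covered. Variants linked to Lepr cannot be told apart from chance placement. Within 10 Mb of the gene 0 of 90 named loci are among the 109 genes, but only 0.71 would be expected. The count depends on the window, since Gm12635 (from 90120058) and Skint3 (from 111961264) of the 109 lie just outside it. On all of chromosome 4, 8 of 918 tested genes are among the 109. Of the 6 unnamed loci 1 lies within the window (chromosome 4, 92474467 to 92474787). Reads moved between class I paralogs cannot be told apart from a change in level: the summed class I FPKM was 0.979 times the nondiabetic value in marrow and 1.252 times in wound, but 3.826 and 3.56 times without the pseudogene H2-M6-ps, which ranged from 0 to 29693 FPKM within a group, so the choice of sum decides the outcome. The labels give the strain as C57BL/6 for all 8 libraries, which taken alone would go against another haplotype. The label was not checked against the reads, so it does not settle whether the haplotypes differ. Of the transcripts of the region among these genes, 10 were higher and 0 lower in diabetic pools, with H2-Ea-ps at 3.47 in wound and 4.55 in marrow. Genotype is confounded with any difference in background, and an effect of diabetes on these genes was not tested.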

How the results depend on the processing

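The settings with unnamed loci, failed estimates kept, loci on the annotated strand, and loci under 200 bp left out were chosen after seeing the data. With the estimated correlation camera called 0 of the 96 list results that passed in the 5 contrasts. Over all 2381 runs of these list results, 2218 kept camera's direction and call, 162 lost the call, and 1 lost it with camera's direction turned. The robust fit does not enter camera, so its 96 runs repeat the main result and could not differ. The stricter filter ended 16 calls, median-ratio scaling 10, quantile scaling 7, unnamed loci 5 and leaving out 1 library 20. Of 344 results for single genes named, 321 kept direction and side of the threshold under every setting run. Total counts of changed genes stayed within 1.5 times of those given under every setting except a minimum difference of 1 on the log2 scale, which left 6501, 6278, 708, 571 and 1263 genes in the order of the contrasts, since it only adds a condition. Genes sharing a direction between the tissue contrasts numbered 6679 (stricter filter, fewer genes tested) to 11691 (unnamed loci). The correlation of diabetes effects across genes was 0.202, and went to 0.295 with unnamed loci and to 0.108 with loci under 200 bp left out; the cause was not tested.

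The oxidative phosphorylation list in diabetic wound against marrow turned to a median of 0.019 under quantile scaling. The list medians also changed sign for fibroblast (0.048, pseudocount of 0.1) and T and NK cell genes (0.065, stricter filter) in the difference between tissues, and for NF-kB targets in marrow (-0.033, without diabetic marrow pool 1). Under quantile and median-ratio scaling, Cxcr2 in marrow was 0.055 and 0.145, Il1b in marrow 0.031 and 0.08, and the Ly6g difference between tissues -0.153 and -0.172. Hoxa3 in diabetic wound against marrow was -0.346 under quantile scaling, and the Itgb2l difference -0.271 with a pseudocount of 0.1. On the annotated strand, Rpl39l in wound was -0.219, Slc9a5 -0.047 and Cxcr2 0, and the Cxcr2 difference 0.047. Without single libraries, Cxcr2 in marrow ranged from -0.095 to 0.085, Il1b in marrow from -0.14 to 0.002, and Hoxa3 in diabetic wound against marrow from -0.019 to 0.321. The cause was not tested for these.

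The samples share a pool number, but the labels do not say that pools of 1 number belong together. With the pool number as a block limma called 11332, 11151, 6711, 5750 and 6770 genes, and camera 94 lists. The 2 lists that did not pass were apoptosis genes in nondiabetic wound against marrow (0.0561) and ribosomal protein genes in the difference between tissues (0.0659). For that difference Myl6 (0.0798) and Slc9a5 (0.0524) did not pass and Hoxa3 did (-0.464, 0.0428), as it did in nondiabetic wound against marrow (0.615, 0.00392). The block changed no other call named. The deviations of wound and marrow pools with 1 number correlated across genes at -0.13 and -0.097 within a genotype, against -0.176 to 0.22 for the other pairs of groups. Where 1 library is left out, the remaining one of its group is assumed to vary like the other groups. The depth is unknown, so counting error could not be separated from spread between pools.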

Other observations

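The comparison of the interferon-response list between tissues was planned; the tests of scaling and of monocyte and dendritic cell share were chosen after the result was seen, and so were the genes named in the next paragraph.

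Genes that changed 2-fold the same way in the diabetic pools of both tissues included H2-Ea-ps, a class II pseudogene of the H2 region, which was measured at 1.46 and 1.57 FPKM in nondiabetic marrow, 57.9 and 58.3 in diabetic marrow, 24.7 and 26.5 in nondiabetic wound, and 299 and 288 in diabetic wound. The class I gene H2-M2 was higher by 1.56 in wound and 2.47 in marrow. Transcripts of stefins, inhibitors of cysteine proteases that lie together on chromosome 16, were also higher in both, with Stfa1 at 1.60 in wound and 2.79 in marrow and Stfa3 at 1.40 and 2.72. Stat4, a transducer of interleukin 12 signals, was lower in both (-1.62 and -1.15), as was Padi2, an enzyme that citrullinates proteins (-1.20 and -1.82).

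Interferon-response genes were lower in the diabetic pools of both tissues. With an estimated correlation the list passed in neither (adjusted p = 0.293 in wound and 0.395 in marrow by camera). The list did not pass for the difference between tissues, though 12 members differed upward and 15 downward. Scaling of the deposited values is argued against as the cause: over quantile and median-ratio scaling the list median ranged from -1.114 to -0.633, with an upper quartile of -0.398 at most. Fewer monocytes and dendritic cells among the diabetic cells would also lower the markers of those cells. For 30 monocyte and dendritic cell genes outside the list the median was -0.184 in wound and -0.238 in marrow. The list median lay below it by -0.817 in wound (permutation p = 1e-05, the smallest possible) and -0.553 in marrow (permutation p = 8e-05). This gap goes against a like loss of both cell types as the whole cause. In wound the dendritic cell list alone fell further than the pooled median, while the monocyte list did not pass. Dendritic cell genes were not compared on their own, so fewer dendritic cells alone stay open as untested. The permutation shuffled genes as if independent, with the medians known, so its p-values do not measure spread between pools. The pattern could reflect lower interferon signalling in diabetic mice, but a difference in strain background between the genotypes stays open, although the labels give C57BL/6 for all 8 libraries, and neither was tested.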
